A study of Mus musculus with 16 samples.

How the data were processed

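Gastrocnemius RNA from 16 mice was sequenced from stranded poly(A) libraries, per the labels' protocols, with 4 mice in each of 4 groups. The deposited values are RPKM, reads scaled to gene length and library total, computed by the authors from trimmed reads, per the file headers. The genome build was mm10, per the submitters' processing notes. The aligner, the counting program, the gene annotation, the use of strand in counting and any filter are not given in the sources used here. Columns were assigned to groups through the mouse identifiers in the labels, and all 16 value columns were used. Of 23440 genes, 6038 were at 0 in every library. No scaling between libraries beyond the total is recorded.

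Within a gene, low RPKM values are whole multiples of what 1 read is worth. The length of each gene and the total of each library were solved from these steps, which gave whole reads for 99.99% of values above 0 within 0.01 read, over 17377 of the 17402 genes above 0 somewhere. Solved totals ran from 16307025 to 20074677 reads, a ratio of 1.23, and the largest relative difference between recomputed and deposited RPKM was 0.00064. The recovered reads were used for depth, for the floor of 3 reads that a count of 0 allows and for 1 alternative test; intervals and floors cover counting error only.

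The design written before the data were examined assumed raw counts with a fallback for normalized values. The file held RPKM rather than counts, so the fallback was used: log2(RPKM + 0.1), genes with at least 1 RPKM in at least 4 of 16 libraries (10171 genes), and limma 3.58.1 with a mean-variance trend and robust moderation (statmod 1.5.0) in R 4.3.3. A single fit with 1 mean per group over all 16 libraries gave 5 contrasts: training in WT, training in KO, the difference of those responses, and KO against WT in untrained and in trained mice. Fold changes are on the log2(RPKM + 0.1) scale, which understates the change of genes at low levels. P-values were two-sided and adjusted by Benjamini-Hochberg within each contrast, with a threshold of 0.05. Alternatives that need deposited raw counts were not run.

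The 33 gene lists, for pathways, neighbours of Il13 and markers of cell types that a muscle sample could hold, were fixed before the data were examined. Of these, 29 had at least 5 members among the tested genes and were tested with camera at its preset correlation of 0.01, adjusted over lists. The 4 lists with fewer members were not tested. Each list was also tested with camera at an estimated correlation, with fry and by exact permutation of the 4 against 4 library means. Members were in addition adjusted over the list alone.

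Genes were named by a rule fixed in advance. The rule takes, in each contrast, up to 8 genes in each direction with the largest change among those past the threshold whose groups of 4 did not overlap (no such condition for the difference of responses), and the 5 with the smallest p where fewer than 5 passed. It adds up to 4 members of each list with the smallest p, and Il13, Il4, Il13ra1, Il13ra2, Il4ra, Stat3, Stat6, Esrra, Esrrg, Ppargc1a and Nnt. Unnamed gene models were skipped, and some genes that the rule names are not reported. Which of the genes that the rule names are printed was chosen after their values were seen, as were Hccs, Timm21, Ank2 and Penk where the text says so. Barx2, Comp and Hspb6 were chosen in that way too where they are given for the difference of responses under other settings.

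The fit was tested on simulated data for the WT training contrast, with 10195 genes drawn at the real means and depths. It recovered 61.2% of genes changed 1.5-fold, 97.9% at 2-fold, 98% at 3-fold and 100% at 4-fold, and called 6 of 9999 unchanged genes. Genes were drawn independently of each other, so these rates do not cover variation shared by the genes of a library. The median SE was 0.1311 in the simulated and 0.1032 in the real data. Altogether 32 alternative settings were run, 16 of which left out 1 library each. The others were quantile normalization, no filter on low values, a filter at 5 RPKM, pseudocounts of 0.01 and 0.001, only the groups compared, the replicate number as a block, weights per library, an adjusted p under 0.1, other list tests and, chosen after seeing the data, voom on the recovered reads, the share of reads in listed genes as a covariate, both KO libraries numbered 3 set aside, quantile normalization of the list tests and exact permutation of list means. Gene overlaps on the genome were taken from GENCODE M21. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery of reads and the plots.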

Results

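Transcript levels were measured by RNA sequencing of poly(A)-selected, stranded libraries from the gastrocnemius, a mixed but mainly fast-fibred calf muscle, of 16 male mice aged 20 weeks. The mice formed 4 groups of 4: wild-type (WT) untrained, WT trained, Il13 knockout (KO) untrained and Il13 KO trained, where training was 5 weeks of daily treadmill running. Each library came from a separate mouse, and the series asks how muscle transcripts respond to endurance training when interleukin-13, a type 2 cytokine, is missing. The deposited table lists 23440 genes with 1 value per library in RPKM, reads scaled to gene length and library total, and 10171 genes reached 1 RPKM in at least 4 libraries and were tested. Library totals solved from the steps between low values ran from 16307025 to 20074677 reads, with a median of 17780533. Myh4, the fast type 2B myosin heavy chain, took the most reads in every library, from 4.70% to 6.47% of these totals. The listed genes held 82.3% ± 1.57 (SD, n = 4) of the solved totals in WT untrained, 78.6% ± 3.51 in WT trained, 79.9% ± 1.95 in KO untrained and 76.7% ± 1.27 in KO trained libraries. The difference with training was -3.71 percentage points in WT (two-sided exact permutation p = 0.143) and -3.22 in KO (p = 0.0857), where 0.0286 is the smallest p that 4 against 4 allow. No sequencing batch or date is given for any library.

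Il13 itself (chromosome 11, 53631323 to 53634702, mm10) had 0 reads in all 8 WT libraries. In KO untrained libraries it had 2, 1, 0 and 0 reads, and in KO trained libraries 0, 1, 0 and 1. A count of 0 allows up to 3 reads, which was 0.124 to 0.153 RPKM in these libraries and covers counting error only. Il13 was therefore not detectable at this depth in WT muscle, and its reads could not check the genotype labels. Il4, its neighbour and close relative among cytokines, had 0 or 1 read in each library. Il13ra1, the signalling receptor subunit for interleukin-13, averaged 0.740, 0.838, 0.826 and 0.868 RPKM in the 4 groups in the order above and was under the filter. Il13ra2, the decoy receptor, had 0 reads in every library. Nnt, a mitochondrial transhydrogenase that is partly deleted in some C57BL/6J stocks, had between 423 and 930 reads in each library. These are reads over the whole gene, so they do not show whether part of it is missing.

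The first comparison asked what training changed in WT muscle. Lpl, the lipase that frees fatty acids from circulating triglyceride, rose from 85.5 ± 15.3 to 152 ± 14.2 RPKM (mean ± SD, n = 4 per group), a 1.80-fold change. Myh2, the fast oxidative type 2A myosin heavy chain, rose 1.65-fold from 381 ± 21.6 to 632 ± 79.0 RPKM, and Fhl1, a LIM protein of the sarcomere, rose 1.59-fold from 213 ± 25.7 to 337 ± 19.8 RPKM. Oxct1, which starts ketone body use in mitochondria, rose 1.39-fold from 89.6 ± 5.40 to 125 ± 2.32 RPKM. Tpm1, the fast-muscle alpha tropomyosin, fell from 6299.7 ± 325 to 5120.3 ± 221 RPKM, and Tbx1, a T-box transcription factor, fell from 3.16 ± 0.428 to 1.39 ± 0.232 RPKM.

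In all, 19 genes changed with training in WT at an adjusted p under 0.05 (limma), 13 higher and 6 lower, with a median size of 0.52 on the log2 scale. The largest rises by fold were Tm6sf1 (log2 fold change 0.92, SE 0.18, adjusted p = 0.0445), Lpl (0.85, SE 0.15, adjusted p = 0.0365), Khdrbs3, an RNA-binding protein (0.77, SE 0.13, adjusted p = 0.0322), and Frzb, a secreted Wnt antagonist (0.74, SE 0.14, adjusted p = 0.0365). Myh2 (0.72, SE 0.13) and Fhl1 (0.67, SE 0.11) followed with adjusted p of 0.0365 and 0.0322, then Got1, the cytosolic aspartate aminotransferase (0.57, adjusted p = 0.0415), and Oxct1 (0.48, SE 0.07, adjusted p = 0.0185). The falls were Tbx1 (-1.13, SE 0.22, adjusted p = 0.0445), the adaptor Shc2 (-0.93, SE 0.14, adjusted p = 0.0185), the lysine methyltransferase Smyd2 (-0.52), the glucose-6-phosphate transporter Slc37a4 (-0.46), the glycolytic regulator Pfkfb4 (-0.46) and Tpm1 (-0.30, adjusted p = 0.0365). Etfa and Acsl1, described below, and 3 genes outside the naming rule that were chosen after their values were seen, Hccs (0.38, adjusted p = 0.0265), Timm21 (0.48, adjusted p = 0.0365) and Ank2 (0.47, adjusted p = 0.0415), make up the rest. The 4 trained and 4 untrained values did not overlap for any of the 19 genes. Chance gives no overlap for 2.86% of genes, and 6.37% of all genes tested showed none. Exons of Smyd2, Ank2, Acsl1, Shc2, Myh2, Oxct1 and Hccs overlap those of a gene on the other strand, so their levels are uncertain where strand was not used in counting. Those of Tm6sf1 also overlap a gene on its own strand, so its level is uncertain either way.

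Leaving out 1 library moved the count from 19 to 0 without WT untrained 3, WT trained 3 or WT trained 4, to 6 without WT untrained 1, to 5 without WT untrained 4, to 10 without WT trained 2 and to 272 (67 higher, 205 lower) without WT trained 1. At an unadjusted p under 0.05 there were 1202 genes, where chance would give 508.6, and weighting libraries by their scatter gave 329 (109 higher, 220 lower).

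Gene lists fixed in advance moved together in trained WT muscle. Genes of fatty acid uptake and oxidation rose as a group (camera adjusted p = 8.66e-18; adjusted p = 0.33 with an estimated correlation). Of its 40 measured members 37 lay above 0, 3 passed over all genes and 22 rose and 1 fell when adjusted over the list alone. The median of 0.27 was 0.17 without WT trained 1. The 3 were Lpl, Etfa, which passes electrons from fatty acid oxidation to the respiratory chain (log2 0.37), and Acsl1, which activates long-chain fatty acids (0.47, 93.5 ± 10.4 to 129 ± 9.27 RPKM). The tricarboxylic acid cycle list rose (adjusted p = 2.33e-12; adjusted p = 0.33 with an estimated correlation), with 23 of 23 members above 0 and 13 passing when adjusted over the list alone, though 0 passed over all genes. Mdh1, the cytosolic malate dehydrogenase, had a log2 difference of 0.43 (adjusted p = 0.0508) and Dld, a subunit of several dehydrogenase complexes, 0.23 (adjusted p = 0.073). Oxidative phosphorylation also rose (adjusted p = 0.000107; adjusted p = 0.98 with an estimated correlation) by a smaller median of 0.07, with 0 of 79 members passing over all genes or when adjusted over the list alone. This rise rested on WT trained 1, without which the median was 0.0237 (adjusted p = 0.0864). It was 0.0312 without WT untrained 1 and 0.11 without WT untrained 2. Exact permutation of the library means gave p = 0.514.

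The slow oxidative fibre list rose by a median log2 of 0.70 (adjusted p = 1.99e-14; adjusted p = 0.208 with an estimated correlation), with 2 of 18 members passing over all genes, Myh2 and Fhl1, and 14 when adjusted over the list alone. Casq2, the slow-muscle calsequestrin, had a log2 difference of 0.72 (adjusted p = 0.0543) and Ckmt2, the mitochondrial creatine kinase, 0.53 (adjusted p = 0.0567). The fast glycolytic fibre list fell (adjusted p = 4.33e-16; adjusted p = 0.194 with an estimated correlation), with 1 of 19 members passing over all genes, Tpm1, and 16 lower and 1 higher when adjusted over the list alone. Mylpf, the fast regulatory light chain, differed by -0.27 (adjusted p = 0.0547) and Actn3, the fast-fibre actinin, by -0.33 (adjusted p = 0.0547). Quantile normalization, which pins the most abundant genes to their rank, gave Tpm1 a difference of 0. Glycolysis and glycogen genes fell as a group (adjusted p = 7.38e-06; adjusted p = 0.353 with an estimated correlation), with 0 of 26 passing over all genes and 9 lower and 1 higher when adjusted over the list alone. Pygm, the muscle glycogen phosphorylase, differed by -0.28 (adjusted p = 0.0608), while Gbe1, the glycogen branching enzyme, differed by 0.35 (adjusted p = 0.129).

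Markers of tendon moved with these groups. The tendon list rose by a median of 0.74 (adjusted p = 1.13e-08; adjusted p = 0.33 with an estimated correlation), with 0 of 12 members passing over all genes and 9 when adjusted over the list alone. Prg4, lubricin, measured 6.31 ± 0.623 RPKM in untrained and 12.5 ± 1.92 in trained WT (log2 0.97, adjusted p = 0.0513), and Comp, a cartilage and tendon matrix protein, 4.69 ± 0.0829 and 9.47 ± 1.03 RPKM (log2 0.99, adjusted p = 0.131). Angiogenesis genes rose (adjusted p = 0.000197; adjusted p = 0.489 with an estimated correlation), with 0 of 17 passing over all genes and 5 when adjusted over the list alone, among them Fgf1 (0.45) and Angpt1 (0.57). The mitochondrial ribosome, import and biogenesis list rose (adjusted p = 0.0103; adjusted p = 0.823 with an estimated correlation), with 0 of 33 passing over all genes and 4 when adjusted over the list alone, including Mfn1, a fusion GTPase of the outer membrane (0.28). Myokines rose (adjusted p = 0.0379; adjusted p = 0.353 with an estimated correlation), with 0 of 9 passing over all genes and 2 when adjusted over the list alone, as for Fndc5, the irisin precursor (0.42). Heat shock genes rose (adjusted p = 0.0273; adjusted p = 0.96 with an estimated correlation), with 0 of 23 passing either way. Leaving out 1 library ended the call of the mitochondrial ribosome list without WT untrained 1 (adjusted p = 0.0795) or WT trained 1 (0.0616). The myokine call ended without WT untrained 3 (0.156), WT trained 2 (0.0962), WT trained 3 (0.106) or WT trained 4 (0.0548). That of heat shock genes ended without WT untrained 1 (0.191), WT untrained 3 (0.173), WT trained 2 (0.0607) or WT trained 3 (0.0839). The other 18 lists tested had adjusted p from 0.08 to 0.951, and markers of macrophages (0.949), endothelium (0.928), adipocytes (0.534), nerve (0.951) and smooth muscle (0.821) were among them. With libraries rather than genes as the unit, exact permutation of the list means gave p = 0.0286, the smallest possible, for the fatty acid, tricarboxylic acid cycle, slow fibre, fast fibre and tendon lists, and an adjusted p of 0.166 for each, where at least 17 of the 29 lists must reach that p for any to pass.

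**Figure D1:**
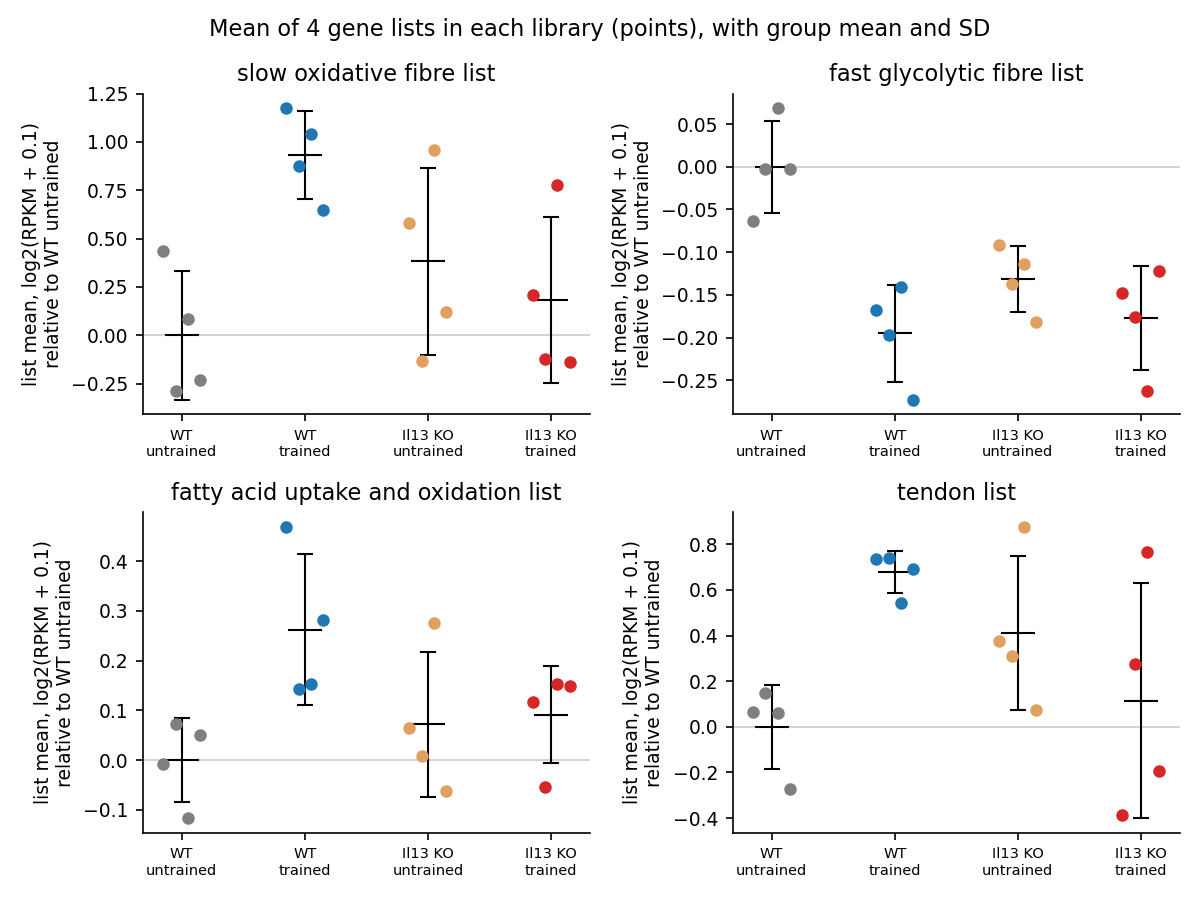
Mean log2(RPKM + 0.1) of 4 gene lists in each of the 16 libraries relative to the WT untrained mean, with the mean and SD of each group of 4. In trained WT muscle the slow fibre list stood at 0.93 ± 0.23, the fatty acid list at 0.26 ± 0.15, the tendon list at 0.68 ± 0.09 and the fast fibre list at -0.19 ± 0.06.

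**Figure D2:**
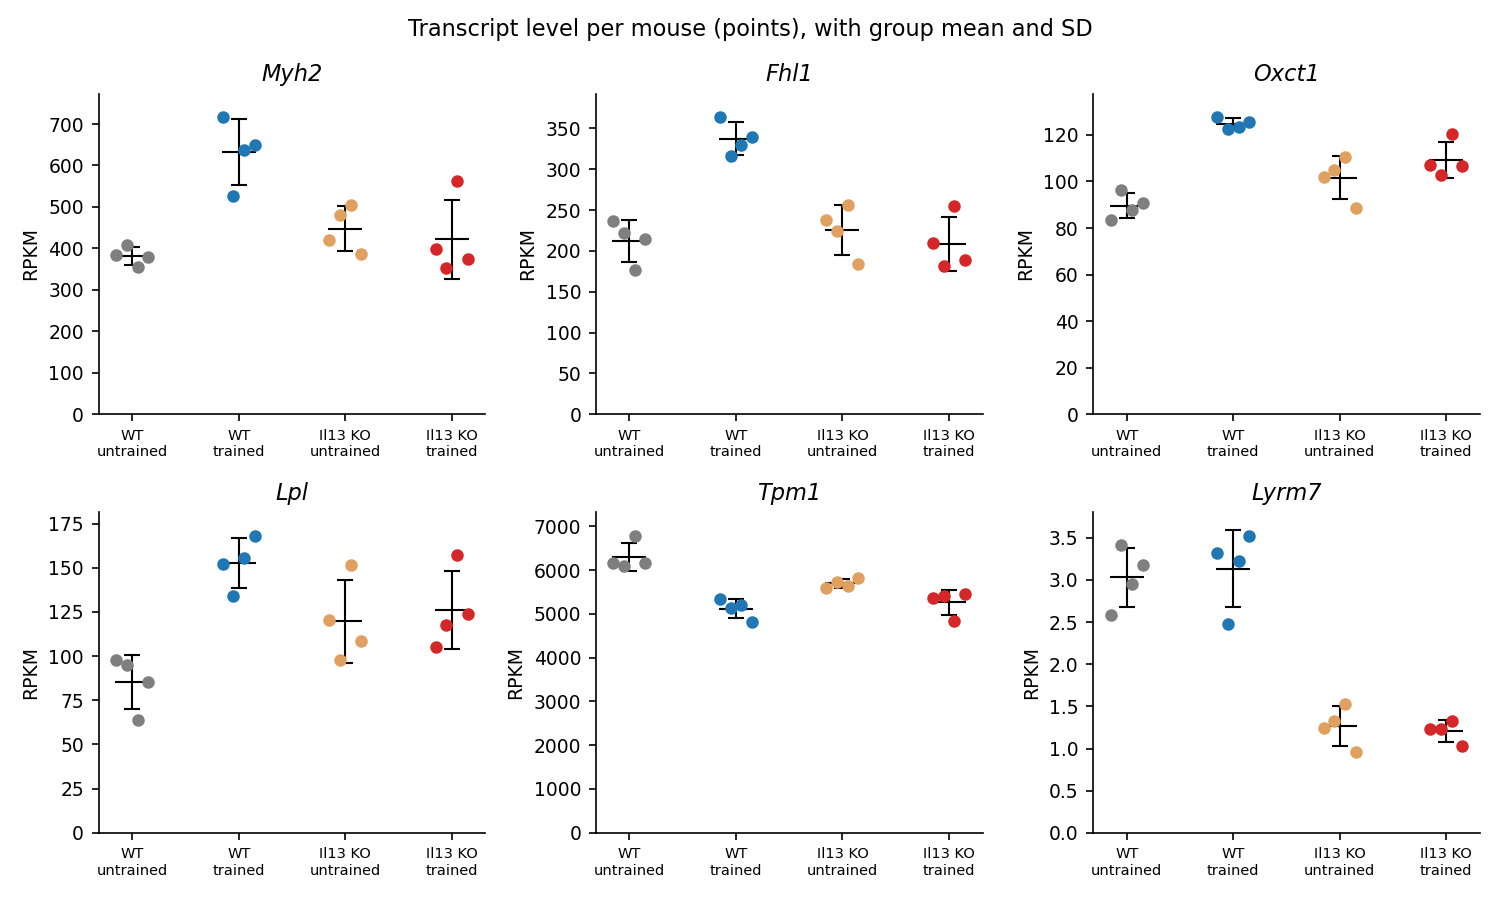
RPKM of 6 genes in each mouse (points), with the mean and SD of each group of 4. The 4 trained WT values of Oxct1 lie between 122 and 128 RPKM, above the untrained WT values of 83.7 to 96.5, while Lyrm7 is lower in both KO groups.

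The second comparison asked what training changed in Il13 KO muscle. No single gene passed: limma gave 0 genes at an adjusted p under 0.05, with 1398 at an unadjusted p under 0.05 against 508.6 by chance and a smallest adjusted p of 0.139. Training in WT had 1202 genes at an unadjusted p under 0.05. The groups of 4 did not overlap for 9.43% of all tested genes in KO and 6.37% in WT, where chance gives 2.86%. The count of 0 therefore does not show that fewer genes moved in KO. Genes that rose in WT were as follows in KO muscle: Lpl measured 119.6 ± 23.3 RPKM untrained and 126 ± 22.2 trained, Myh2 448 ± 53.7 and 422 ± 95.1, and their log2 differences were -0.12 for Fhl1 (adjusted p = 0.654) and 0.11 for Oxct1 (adjusted p = 0.478; n = 4 per group). The genes with the smallest p were higher for Ireb2, an iron-regulatory RNA-binding protein (log2 0.42), the nuclear exporter Xpo1 (0.59), the small GTPase Rab18 (0.28), Zfp120 (0.66) and Naa50 (0.35). They were lower for Dlgap4 (-0.35), Zrsr1 (-0.47), Prkcdbp, a caveolar coat protein (-0.59), and Mospd3 (-0.50), and each of these 9 had an adjusted p of 0.139.

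As a group, extracellular matrix and collagen genes fell with training in KO muscle (camera adjusted p = 0.000907; adjusted p = 0.854 with an estimated correlation). All 32 members measured lay below 0, by a median of -0.30, and 0 passed over all genes or when adjusted over the list alone. The median of all tested genes was itself -0.0557, so a count below 0 is not by itself particular to a list. Sparc, a matrix glycoprotein, measured 164 ± 33.5 RPKM untrained and 123 ± 25.1 trained, the collagen cross-linking enzyme Lox 3.38 ± 0.559 and 2.44 ± 0.694, and the proteoglycan Bgn 33.6 ± 3.66 and 25.9 ± 4.81. Nerve and Schwann cell markers fell too (adjusted p = 0.0334; adjusted p = 0.854 with an estimated correlation), with 7 of 7 below 0 and 0 passing either way, such as the myelin genes Cnp (-0.43), Prx (-0.64) and Mbp (-0.74). Other cell markers lay lower without passing: 13 of 13 adipocyte (adjusted p = 0.0504), 10 of 11 smooth muscle (0.0539), 14 of 14 fibro-adipogenic progenitor (0.0937), 12 of 12 tendon (0.0963) and 11 of 11 macrophage members (0.149) were below 0. The other 27 lists, these among them, had adjusted p from 0.0504 to 0.886. They included fatty acid oxidation (0.0516, mean log2 difference 0.0195), the tricarboxylic acid cycle (0.0504, 0.0228) and the slow fibre list (0.637, -0.2013). Voom on the recovered reads also gave 0 genes, weighting libraries by their scatter gave 97 (41 higher, 56 lower), and leaving out KO trained 3 gave 1, Penk (-0.63, adjusted p = 0.0385), named after its value was seen. The 2 lists became 9 without KO untrained 1, 6 without KO untrained 3, 8 without KO trained 2, 9 without KO trained 3 and 7 without KO trained 4. The nerve call ended without KO untrained 3 (adjusted p = 0.0908) or KO untrained 4 (0.103). The extracellular matrix median was -0.15 without KO untrained 1 and -0.46 without KO untrained 4. Two-sided exact permutation of the library means of that list gave p = 0.171.

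The third comparison, the test of the question itself, set the training response in KO against that in WT. The slow fibre list responded less in KO: its mean rose by 0.93 on the log2 scale in WT and differed by -0.20 in KO, a difference of -1.13 (camera adjusted p = 1.36e-11; adjusted p = 0.294 with an estimated correlation). All 18 members lay below 0 and 12 passed when adjusted over the list alone, though 0 passed over all genes. The median of all tested genes was -0.0495 in this comparison. The tendon list responded less as well, by -0.97 (adjusted p = 2.24e-09; adjusted p = 0.294 with an estimated correlation), with 10 of 12 passing when adjusted over the list alone and 0 over all genes. Two-sided exact permutation of the library means gave p = 0.0216 for the slow fibre and 0.0155 for the tendon list, each with an adjusted p of 0.266. Single genes did not pass: limma gave 0 at an adjusted p under 0.05, with 854 at an unadjusted p under 0.05 against 508.6 by chance and a smallest adjusted p of 0.526.

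The genes with the smallest p in this comparison included Fhl1 (log2 difference of responses -0.79, SE 0.16), Myh2 (-0.82, SE 0.18), Prg4 (-1.31, SE 0.28), Khdrbs3 (-0.82, SE 0.18) and Klf5, a zinc finger transcription factor (-1.22, SE 0.26). In the other direction were Twistnb (0.59), Slc37a4 (0.45), the Mediator kinase Cdk19 (0.52), Hist3h2a (0.52) and Rab18 (0.32), all with an adjusted p of 0.526. Fatty acid genes responded less in KO (adjusted p = 3.07e-08; adjusted p = 0.556 with an estimated correlation), with 36 of 40 members below 0, such as Lpl (-0.77) and Hadha, a subunit of the trifunctional protein (-0.45), and 0 passing over all genes or over the list alone. The tricarboxylic acid cycle (adjusted p = 0.000353), extracellular matrix (3.34e-06), heat shock (0.00103), angiogenesis (0.00181), interferon (0.0072), adipocyte (0.0107), nerve (0.0213) and smooth muscle lists (0.023) also had a lower response in KO than in WT, each with an adjusted p of 0.556 with an estimated correlation. Lower does not always mean a smaller rise. List means differed with training by 0.1821 in WT and 0.0228 in KO for the tricarboxylic acid cycle and by 0.19 and -0.0592 for angiogenesis. Larger falls in KO were seen for heat shock (0.1325 and -0.1678), interferon (0.0654 and -0.2266) and extracellular matrix genes (0.1177 and -0.2829). So it was for adipocyte (0.2021 and -0.4807), nerve (0.0317 and -0.5771) and smooth muscle markers (-0.0036 and -0.2948). Adjusted over the list alone, 3 heat shock genes passed, with Bag3 (-0.51) and the small heat shock protein Cryab (-0.74) showing the smallest p, as did 1 of angiogenesis, where Fgf1 (-0.57) had the smallest, and 0 of the other 6 lists. The fast fibre list was higher (adjusted p = 2.24e-09; adjusted p = 0.294 with an estimated correlation), with Actn3 (0.34) and Mylpf (0.26) showing the smallest p and 2 of 19 passing when adjusted over the list alone. Glycolysis and glycogen was higher too (adjusted p = 0.00566; adjusted p = 0.556 with an estimated correlation), with 0 of 26 passing. Leaving out 1 library ended the call of adipocyte markers without WT trained 3 (adjusted p = 0.0943), KO untrained 3 (0.0548), KO trained 2 (0.0507) or KO trained 4 (0.0587). The interferon call ended without KO trained 1 (0.0706). Nerve markers lost theirs without WT untrained 2 (adjusted p = 0.102), WT trained 1 (0.081), WT trained 3 (0.14), KO untrained 3 (0.0961) or KO untrained 4 (0.0742). Smooth muscle lost its call without WT untrained 4 (0.0606), WT trained 4 (0.0911), KO untrained 2 (0.0932) or KO trained 4 (0.0913). The remaining 16 lists had adjusted p from 0.0523 to 0.754.

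Voom on the recovered reads and weighting by scatter each gave 0 genes. With KO trained 3 left out, 2 genes passed, Prg4 (-1.53, adjusted p = 0.0168) and Myh2 (-0.97, adjusted p = 0.0168), with any other library left out neither passed (adjusted p up to 0.849), and over the 11 alternatives that leave out no single library the adjusted p of each ran from 0.0293 to 0.605.

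The responses of the 2 genotypes shared 0 genes at an adjusted p under 0.05, since KO had none. At an unadjusted p under 0.01 in both, 14 genes were higher and 22 lower in both genotypes, against 3.93 and 4.18 for independent lists, with Cycs, cytochrome c, and Dld among the higher. Of the 19 genes that changed in WT, 16 had the same sign in KO, 19 were smaller and 2 had an unadjusted p under 0.05 there. The median size along the WT direction was 0.52 in WT and 0.08 in KO, a contrast that is in part set by choosing the genes on WT. Across the 10171 genes, which are not independent replicates, the fold changes of the 2 genotypes correlated with Pearson's r = 0.0919 and Spearman's rho = 0.181.

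The fourth comparison asked how untrained KO muscle differed from untrained WT. All 5 genes that passed lie on chromosome 11 near Il13. Lyrm7, a mitochondrial factor for assembly of the Rieske protein into complex III (54839289 to 54860591), was lower at 1.27 ± 0.238 against 3.03 ± 0.351 RPKM (log2 -1.21, SE 0.14, adjusted p = 0.0013, n = 4 per group). Thg1l, a mitochondrial tRNA-histidine guanylyltransferase (45948154 to 45955494), was higher at 3.49 ± 0.606 against 1.48 ± 0.228 RPKM (1.17, SE 0.15, adjusted p = 0.00181). Tnip1, an inhibitor of NF-kappa-B signalling (54910787 to 54962940), was higher at 17.4 ± 1.07 against 12.3 ± 0.272 RPKM (0.49, SE 0.08, adjusted p = 0.0176). Fam114a2 (57482990 to 57518644) was lower at 14.5 ± 0.817 against 19.7 ± 0.784 RPKM (-0.45, adjusted p = 0.00399), and so was Anxa6, a calcium-dependent membrane-binding annexin (54978962 to 55033471), at 56.4 ± 4.82 against 73.0 ± 2.70 RPKM (-0.37, adjusted p = 0.0482).

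Next by p, and not passing, were Fastkd1 (0.40, adjusted p = 0.16), Mospd2 (0.51, adjusted p = 0.385) and Acsl6 (0.33, adjusted p = 0.655) on the higher side and Mylpf (-0.29, adjusted p = 0.16) and Hist3h2a (-0.45, adjusted p = 0.166) on the lower. Values of the 5 genes did not overlap between genotypes, where chance gives 2.86% of genes and 3.95% of all tested showed it. The low level of Thg1l (20 to 67 reads per library) limits its precision. The count was 3 without any 1 of the 4 WT untrained libraries, KO untrained 1 or KO untrained 3, and leaving out 1 library at a time ended the call of Anxa6 in 8 of 8 fits and of Tnip1 in 6, but of Lyrm7, Thg1l and Fam114a2 in 0.

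Among the lists, extracellular matrix genes were higher in untrained KO (camera adjusted p = 9.58e-11), with 32 of 32 members above 0, 0 passing over all genes and 2 over the list alone; its adjusted p = 0.499 with an estimated correlation. Sparc stood at 164 ± 33.5 against 111 ± 7.55 RPKM and Lox at 3.38 ± 0.559 against 2.21 ± 0.188. Two-sided exact permutation of the library means of the extracellular matrix list gave p = 0.171. Relative to WT untrained its mean was 0.31 ± 0.32 (SD) in KO untrained and 0.02 ± 0.19 in KO trained libraries. This higher level, the fall with training in KO and the lower response in KO all rest on the same KO untrained libraries. Oxidative phosphorylation was lower (adjusted p = 6.39e-15; adjusted p = 0.554 with an estimated correlation), with 78 of 79 members below 0 by a median of -0.11 and 0 passing, as in Ndufb4 of complex I (-0.16). The fast fibre list was lower (adjusted p = 5.89e-11; adjusted p = 0.499 with an estimated correlation), with 6 of 19 passing over the list alone, such as Mylpf and the calcium buffer Pvalb (-0.24). Glycolysis was lower (adjusted p = 1.42e-06; adjusted p = 0.499 with an estimated correlation), with 0 of 26 passing, and so was the neuromuscular junction list (adjusted p = 0.00835; adjusted p = 0.554 with an estimated correlation), with 1 of 12 passing over the list alone and Chrnb1, an acetylcholine receptor subunit, at -0.38. The call of the neuromuscular junction list ended without KO untrained 4 (adjusted p = 0.0868). The oxidative phosphorylation median was -0.07 without WT untrained 2 and -0.05 without KO untrained 4. That of extracellular matrix genes went from 0.33 to 0.19 without KO untrained 1.

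Marker lists of several other cell types were higher in untrained KO at the same time. These were adipocyte (adjusted p = 5.6e-06), tendon (2.07e-05), nerve (0.000547), fibro-adipogenic progenitor (0.0176), smooth muscle (0.0312) and macrophage markers (0.0411). The slow fibre (adjusted p = 0.00272), fatty acid (0.0176), myokine (0.0294) and heat shock lists (0.0312) were higher too, and these 10 lists had an adjusted p = 0.499 to an adjusted p = 0.69 with an estimated correlation. Over all genes 0 members of these 10 lists passed. Adjusted over the list alone, 1 member passed in each of the tendon, fatty acid and myokine lists and 0 in the other 7. Cidec, a lipid droplet protein, stood at 17.6 ± 5.97 against 9.11 ± 3.90 RPKM, and Ptx4 of the tendon list at 1.07 ± 0.375 against 0.542 ± 0.162. Of these 10 lists, only adipocyte, tendon and nerve markers passed with any 1 library left out. Their medians depended on KO untrained 3. Without it they went from 0.66 to 0.40 for adipocyte, 0.45 to 0.26 for tendon and 0.54 to 0.27 for nerve markers (camera adjusted p = 0.0398). The direction itself turned for heat shock without KO untrained 1 (median -0.0307, adjusted p = 0.968), macrophage without KO untrained 1 (-0.0408, 0.388), fatty acid without KO untrained 3 (-0.0141, 0.844) and myokine genes without WT untrained 3 (-0.0376, 0.195). Calls ended as well for heat shock without WT untrained 1 (adjusted p = 0.201), WT untrained 3 (0.288) or KO untrained 2 (0.0685). Macrophage markers lost theirs without WT untrained 2 (0.0653), WT untrained 3 (0.363) or KO untrained 2 (0.0654), fatty acid genes without WT untrained 3 (0.195) and myokine genes without KO untrained 1 (0.0699). Calls for fibro-adipogenic progenitors ended without WT untrained 1 (adjusted p = 0.0706), WT untrained 3 (0.0855) or KO untrained 1 (0.0699). Smooth muscle did not pass without WT untrained 1 (0.105), WT untrained 4 (0.125) or KO untrained 2 (0.222), nor slow fibre genes without WT untrained 4 (0.0503) or KO untrained 3 (0.129). The other 14 lists had adjusted p from 0.075 to 0.783.

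The fifth comparison set trained KO muscle against trained WT. Here 9 genes passed, 2 higher and 7 lower, and 4 of them, Lyrm7, Tnip1, Fam114a2 and Anxa6, were those of the untrained comparison in the same direction, where independent lists would share 0 higher and 0.002 lower. Lyrm7 was lower at 1.21 ± 0.127 against 3.14 ± 0.456 RPKM (log2 -1.30, SE 0.14, adjusted p = 0.000455, n = 4 per group), and Anxa6 at 51.7 ± 1.40 against 73.1 ± 5.34 (-0.50, adjusted p = 0.00345). Fhl1 was lower (-0.71, SE 0.11, adjusted p = 0.0224), and Hspb6, a small heat shock protein of muscle, at 446 ± 23.7 against 736 ± 155 (-0.70, adjusted p = 0.0319). Acsl6, an acyl-CoA synthetase whose gene lies at 54303824 to 54361539 on chromosome 11, was higher at 12.9 ± 0.396 against 9.24 ± 0.848 RPKM (0.48, adjusted p = 0.0229).

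Tnip1 (0.48, adjusted p = 0.0224) was higher, and Fam114a2 (-0.38, adjusted p = 0.0224), the paraoxonase Pon2 (-0.65, adjusted p = 0.0324) and Tecr, an enzyme of very long fatty acid synthesis (-0.35, adjusted p = 0.0324), were lower. Thg1l, called in untrained mice, did not pass here (0.34, adjusted p = 0.315), and its groups overlapped. Not passing either were Oaz1 (0.53, adjusted p = 0.132), Lin7c (0.34, adjusted p = 0.145) and Pgm2l1 (0.41, adjusted p = 0.149). Values of the 9 genes did not overlap between genotypes, where chance gives 2.86% of genes and 8.48% of all tested showed it. Exons of Pon2, Hspb6 and Acsl6 overlap those of another gene. The count of 9 was 2 without WT trained 3, WT trained 4 or KO trained 1 and 3 without KO trained 2 or KO trained 4, and the calls of Lyrm7 and Anxa6 ended in 0 of 8 such fits.

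Oxidative phosphorylation genes were lower in trained KO muscle (camera adjusted p = 6.99e-16; adjusted p = 0.959 with an estimated correlation). Of its 79 members 76 lay below 0, 25 passed when adjusted over the list alone and 0 over all genes. All tested genes had a median of -0.0542 in this comparison. Ndufa12 of complex I stood at 247 ± 12.2 against 315 ± 30.7 RPKM and Ndufv2, its flavoprotein subunit, at 177 ± 7.48 against 206 ± 9.88. The slow fibre list was lower (adjusted p = 9.51e-09; adjusted p = 0.959 with an estimated correlation), with 18 of 18 below 0, 1 passing over all genes, Fhl1, and 8 over the list alone, such as the sarcomeric Myoz2 (-0.67). Fatty acid genes were lower (adjusted p = 5.58e-06; adjusted p = 0.984 with an estimated correlation), with 17 lower and 1 higher, Acsl6, when adjusted over the list alone. The tricarboxylic acid cycle was lower (adjusted p = 5.69e-07; adjusted p = 0.959 with an estimated correlation), with 4 of 23 passing over the list alone and citrate synthase, Cs, at -0.21. Tendon markers were lower (adjusted p = 8.19e-05; adjusted p = 0.959 with an estimated correlation), with 5 of 12 passing over the list alone. Angiogenesis (adjusted p = 0.0333) and heat shock (adjusted p = 0.0441) were lower with 2 members each over the list alone, and both had an adjusted p = 0.984 with an estimated correlation. The angiogenesis call ended without WT trained 1 (adjusted p = 0.0683), WT trained 4 (0.147) or KO trained 4 (0.164). The heat shock call ended without WT trained 2 (0.115), WT trained 3 (0.132), WT trained 4 (0.0847), KO trained 1 (0.135), KO trained 3 (0.0798) or KO trained 4 (0.142). The other 22 lists had adjusted p from 0.0708 to 0.959.

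**Figure D3:**
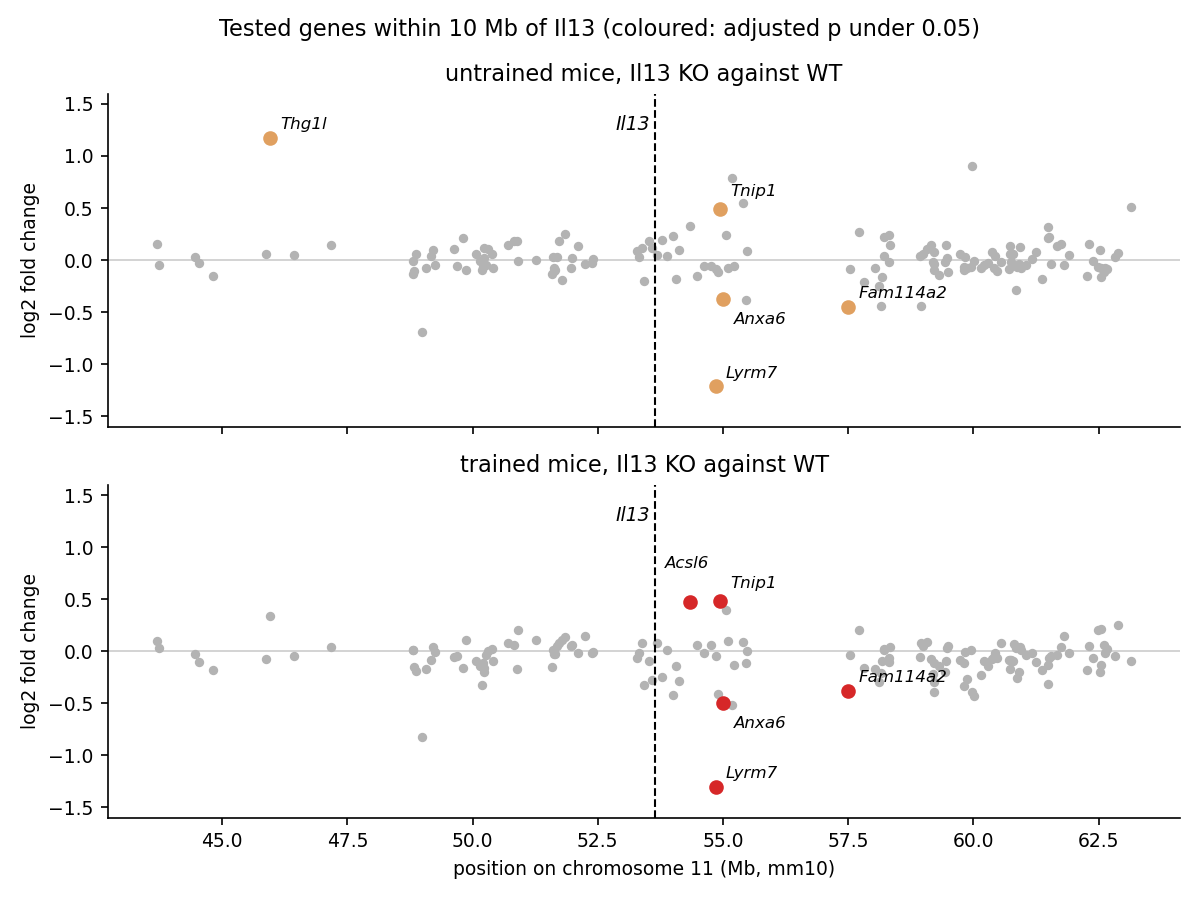
Log2 fold change, KO against WT, of each tested gene within 10 Mb of Il13 by its position on chromosome 11 (mm10), in untrained (top) and trained mice (bottom), with genes past the threshold in colour and the dashed line at Il13. All 5 genes that passed in untrained mice and 5 of the 9 in trained mice lie in this window, which holds 1.56% of the genes tested.

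Genes of the receptor pathway that passed the filter and the regulators of oxidative metabolism given here were tested in every comparison. Il13, Il4, Il13ra1 and Il13ra2 were under the filter and were not tested. Il4ra, the receptor chain shared by interleukin-4 and interleukin-13, had a log2 difference with training of -0.05 in WT (adjusted p = 0.947) and -0.38 in KO (adjusted p = 0.393). Stat3, which transmits cytokine signals to the nucleus, differed by 0.05 in WT (adjusted p = 0.874) and -0.33 in KO (adjusted p = 0.203), and Stat6 by 0.10 (adjusted p = 0.728) and -0.18 (adjusted p = 0.392). The orphan receptor Esrrg measured 4.00 ± 0.452 RPKM in untrained and 5.26 ± 0.351 in trained WT (log2 0.39, adjusted p = 0.154) against 4.26 ± 0.740 and 4.37 ± 0.549 in KO. Esrra differed by 0.15 in WT (adjusted p = 0.62) and Ppargc1a, the coactivator of mitochondrial biogenesis, by 0.13 (adjusted p = 0.898), while in KO they differed by -0.01 (adjusted p = 0.965) and -0.25 (adjusted p = 0.713). Nnt measured 6.60 ± 1.03 and 9.42 ± 1.79 RPKM in untrained and trained WT (adjusted p = 0.109) and 7.21 ± 0.791 and 7.40 ± 1.09 in KO (adjusted p = 0.929). The responses of Stat3 (-0.39, adjusted p = 0.529), Esrrg (-0.35, adjusted p = 0.593) and Nnt (-0.47, adjusted p = 0.55) did not pass the test of a difference between genotypes.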

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

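The tests of where the genotype genes lie, of read mapping, of effects elsewhere in the genome and of a lower share of muscle fibres were chosen only after the result was seen.

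Several genes that differed between genotypes lie near Il13: 159 of the 10171 tested genes are within 10 Mb of it, and all 5 genes called in untrained mice were among them, within a span of 11.57 Mb. Of 9 genes with an unadjusted p under 0.01 and the same sign in untrained and trained mice, 5 were in that window (Fisher's exact p = 1.05e-07), but the window was set after these genes were seen. The list of Il13 neighbours fixed in advance had a camera adjusted p = 0.123 untrained and 0.711 trained, and for either direction (fry) 0.28 and 0.0133. Its tested members lie only from -1.64 Mb (Ube2b) to 0.978 Mb (Rapgef6) of Il13. None of the 5 genes called in untrained mice is in it, so these tests say little about a wider segment. Thg1l, higher by 1.17 in untrained KO, differed by 0.34 in trained mice (adjusted p = 0.315). A chromosome 11 segment carried along with the knockout allele therefore stays open. Sequence variants that lower read mapping are argued against for the 3 higher genes, Thg1l, Tnip1 and Acsl6, since they cannot raise a level over that of WT mice which, by the strain in the sample labels, match the mm10 reference, but for the 3 lower ones, Lyrm7, Anxa6 and Fam114a2, they cannot be told apart from lower expression without the reads. An effect of the missing gene elsewhere also stays open, since 4 genes outside the window met the same rule against 2.14 for independent lists. For the count of genes, 1 of 35 splits of the 8 libraries, the real one, gave as many in untrained mice (5, highest other 3) and in trained mice (9, highest other 1). That is the smallest share that 35 splits allow, and it was not adjusted over the counts tested. Chance is therefore argued against there but not excluded.

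Fatty acid and slow fibre genes rose together in trained WT muscle by the preset camera test. With an estimated correlation 0 lists passed for training in WT (smallest adjusted p = 0.194). Scaling between libraries is argued against, since quantile normalization left the fatty acid list mean 0.28 ± 0.06 (SE) higher, against 0.26 before. A lower share of muscle fibres would raise the markers of every other cell type alike. Of 5 such lists, 4 lay below the tendon list by more than 2 SE, but the tendon list rose most, which made this likely from the start. The endothelial mean differed by 0.0136 ± 0.0796 (SE) and the smooth muscle mean by -0.0036 ± 0.0983, so a rise alike in all lists was not seen. A lower share that comes with more tendon alone is not covered by this comparison. A larger share of slow muscle in the trained samples, by dissection or by training, cannot be told apart: with the mean of 9 slow fibre genes as a covariate the difference was 0.19 ± 0.12 against 0.26 without it. Chance was not excluded for the counts, since 2 of 35 splits gave at least the 19 genes (highest other 71) and 5 of 35 at least the 11 lists (highest other 13), and a split with 71 genes points to a structure of the samples whose source was not tested.

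The slow fibre list responded less to training in KO by the preset camera test, by -1.13 on the log2 scale. For the difference of responses 0 lists passed with an estimated correlation (smallest adjusted p = 0.294) or with fry (0.123). Exact permutation gave the slow fibre list an adjusted p of 0.266. Without both KO libraries numbered 3, which had the highest slow fibre means of their groups, the difference was -1.14 ± 0.31 (SE), and with the share of reads in listed genes as a covariate -1.15 ± 0.40. Neither setting removed the difference, but both could shift it only little. Leaving out the highest library of each KO group lowers both means. The share itself differed by only 0.489 percentage points in this contrast (two-sided exact permutation p = 0.871). Chance was not excluded for the lists, since 14 of 100 splits gave at least 13 (highest other 19), while the count of 0 genes decides nothing, as all 100 splits must give at least that (highest other 76). Whether the difference comes from interleukin-13 or from other genes near Il13 was not tested, since the design ties them together. A different share of slow muscle in the samples was not tested for this difference either. Myh7 ran from 8.24 to 68.4 RPKM within KO trained muscle, and the slow fibre mean of untrained KO already lay 0.38 above that of untrained WT.

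For the other list counts, all 35 splits gave at least the 2 lists of training in KO (highest other 15), 2 of 35 at least the 15 lists of the untrained genotype comparison (highest other 15) and 17 of 35 at least the 7 lists of the trained one (highest other 13), so chance was not excluded for any of these. The count of 0 genes for training in KO decides nothing, as all 35 splits must give at least that (highest other 71).

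The responses of 13 lists differed between genotypes by the preset camera test, with mean differences (KO minus WT, log2) of -1.13 for slow fibre, -0.97 for tendon, -0.68 for adipocyte, -0.61 for nerve, -0.40 for extracellular matrix, -0.30 for heat shock, -0.29 (-0.292) for interferon, -0.29 (-0.2913) for smooth muscle, -0.25 for angiogenesis, -0.24 for fatty acid, -0.16 for tricarboxylic acid cycle, 0.15 for fast fibre and 0.0258 for glycolysis genes. With an estimated correlation 0 lists passed (smallest adjusted p = 0.294), as with fry (0.123) and exact permutation (0.266). Leaving out 1 library moved some medians by over 1.5 times. Without KO untrained 3 the adipocyte median went from -0.83 to -0.52 and the nerve median from -0.66 to -0.3669 (-0.3676 without WT trained 1). Heat shock went from -0.22 to -0.12 without KO untrained 1 and the tricarboxylic acid cycle from -0.13 to -0.21 without KO untrained 4. Glycolysis went from 0.0682 to 0.1196 without WT untrained 1, 0.1029 without WT trained 1, 0.113 without KO trained 3 and 0.044 without KO trained 4.

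In 39 of 624 groups of 4 libraries, where chance gives 31.2 (about 1 in 20), 1 library stood so far from the other 3 that its gap divided by the group's range passed Dixon's critical value. WT trained 1 and KO untrained 3 did so most often, 6 times each, and WT trained 1 had the lowest weight of any library, 0.309. In WT untrained, library 3 stood lowest for Tbx1 (0.849), Sparc (0.833) and Tnip1 (0.83) and highest for Tpm1 (0.878) and Pvalb (0.869), while library 1 stood lowest for Fam114a2 (0.863) and for the share of reads in listed genes (0.882) and highest for Cidec (0.939). In WT trained, library 1 stood highest for Tnip1 (0.892), Anxa6 (0.907) and the oxidative phosphorylation (0.871), tricarboxylic acid cycle (0.835) and macrophage lists (0.832) and lowest for Ptx4 (0.898). Library 2 of that group stood lowest for Timm21 (0.871) and the receptor signalling list (0.905) and highest for Twistnb (0.885), and library 4 lowest for Mylpf (0.914).

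In KO untrained, library 1 stood highest for Il13ra1 (0.832) and the atrophy list (0.988), and library 3 highest for Esrrg (0.896), Comp (0.852), Oasl2 (0.876), Pmp22 (0.901), Barx2 (0.87) and Fmod (0.885). Library 4 stood lowest for Mfn1 (0.915), Pdgfrb (0.849) and Cd34 (0.854) and highest for Ireb2 (0.841). In KO trained, library 3 stood highest for Khdrbs3 (0.853), Cryab (0.841), Plin1 (0.942) and the angiogenesis list (0.85) and lowest for Tpm1 (0.878). Library 2 stood lowest for Ndufb6 (0.89) and the nerve list (0.862), and library 4 highest for the list of Il13 neighbours (0.832) and lowest for Myh11 (0.947).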

How the results depend on the processing

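Voom on recovered reads, the share of reads in listed genes as a covariate, both KO libraries numbered 3 set aside, quantile normalization of list tests and exact permutation of list means were chosen only after the result was seen. The counts of genes that changed with training in WT depended on the setting: against 19 there were 155 with quantile normalization, 3 with no filter, 58 with a filter at 5 RPKM, 35 with only the groups compared, 329 with weights per library, 136 at an adjusted p under 0.1, 64 with voom and 78 (74 higher, 4 lower) with the share as covariate, and 0 to 272 with 1 library left out. For training in KO, against 0, there were 1 with no filter (an unnamed gene model), 97 with weights per library and 0 to 1 with 1 library left out. For the difference of responses, against 0, there were 1 with quantile normalization (Hspb6, -0.66, adjusted p = 0.0309), 1 with no filter (the same unnamed model), 0 to 2 with 1 library left out and 4 with both KO libraries numbered 3 set aside: Prg4 (-1.44, adjusted p = 0.0293), Comp (-1.17, 0.0293), Barx2 (-1.25, 0.032) and Myh2 (-0.91, 0.0293). For KO against WT untrained, against 5, there were 3 with a filter at 5 RPKM, with only the groups compared and with the KO libraries numbered 3 set aside, and 3 to 5 with 1 library left out. For KO against WT trained, against 9, there were 3 with only the groups compared, 24 with the KO libraries numbered 3 set aside and 2 to 9 with 1 library left out. The overlap of the training responses was 0, and 36 at an unadjusted p under 0.01 in both.

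List counts fell to 0 in all 5 contrasts with an estimated correlation, and with fry to 2 for training in WT (slow and fast fibre) and to 0 in the other 4. Exact permutation gave 0 in all 5, which for 4 against 4 libraries says little, since at least 17 of 29 lists would have to reach the smallest p, 0.0286. For the difference of responses the smallest p, 0.000408, left room to pass. The 2 lists of training in KO, both lower, became 13 with quantile normalization (3 higher, 10 lower) and 9 with the share as covariate (4 higher, 5 lower). They became 12 with the KO libraries numbered 3 set aside (3 higher, 9 lower). With 1 library left out, list counts ran from 9 to 13 for training in WT, 2 to 9 for training in KO, 12 to 16 for the difference of responses, 10 to 18 untrained and 5 to 8 trained. Except where fewer genes, libraries or list units enter by construction, the cause was not tested.

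Directions changed, or differences went to 0, as follows. Quantile normalization gave 0 for Tpm1, which held the same rank in every library, in training in WT and in the difference of responses, 0 for Eno3 in untrained mice, 0.0005 for Uqcrb in trained mice and 0.0359 for Esrra in training in KO. With 1 library left out, Il4ra in WT training ran from -0.1552 to 0.0653, and in KO training Esrra ran from -0.0892 to 0.044, Esrrg from -0.0153 to 0.1568, Ppargc1a from -0.4693 to 0.0961 and Nnt from -0.0625 to 0.1025. In untrained mice the heat shock list ran from -0.0307 to 0.1948, the fatty acid list from -0.0141 to 0.0904, the macrophage list from -0.0408 to 0.3401 and the myokine list from -0.0376 to 0.3203. The share as covariate gave 0.1789 for Il4ra in WT and 0.1261 for Esrra in KO training, and setting aside the KO libraries numbered 3 gave 0.0164 for Esrra there and -0.0141 for the fatty acid list in untrained mice. Over 254 comparisons of named genes, 5088 values kept direction and side of the threshold, 124 gained it, 194 lost it and 20 changed sign or went to 0, and for lists 600 kept both, 160 lost the threshold and 5 changed direction. Pseudocounts of 0.01 and 0.001 left every count of genes the same.

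Replicate numbers were not taken to pair the samples, since the labels name no shared litter, batch or day and not every pair had a correlation over 0.1: same-numbered libraries had correlations of deviations of -0.113, -0.0495, 0.0441 and 0.109 for WT training and 0.149, 0.191, 0.442 and 0.0523 for KO training, and 1 of 4 WT and 3 of 4 KO pairs correlated best with their own number, a hint from the data for KO only. The mouse identifiers are consecutive within every same-numbered KO pair, which leaves a pairing of KO mice open. Identifiers of WT and KO mice also form separate ranges, and whether these mark separate cohorts is not given. With the number as a block, counts were 16, 0, 0, 4 and 5 genes and 12, 7, 14, 15 and 7 lists in the 5 contrasts in the order above. Of the 7 lists of training in KO, 2 were higher and 5 lower. At this depth the limit is for genes near the floor, such as Il13.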

Other observations

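No test reported in this part was chosen only after the result was seen, but the genes and lists described were picked after their values were known.

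The following lists did not pass for training in WT, whatever the size of their mean difference. The circadian clock list (mean log2 difference -0.02, camera adjusted p = 0.821), immediate early genes (0.01, 0.648) and glucose uptake and insulin signalling (0.02, 0.951) were among them, as were regulators of the ERR and PGC-1 family (0.10, 0.312), atrophy and ubiquitin ligases (-0.18, 0.08), interferon response (0.07, 0.534) and receptor signalling of interleukin-13 and interleukin-4 (0.12, 0.821). Among cell type markers, alternatively activated macrophages (-0.09, 0.821), satellite cells and regeneration (0.05, 0.91), the neuromuscular junction (-0.02, 0.821) and fibro-adipogenic progenitors (0.05, 0.821) did not pass either, nor did extracellular matrix (0.12, 0.091) or the neighbours of Il13 (0.07, 0.111).

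Slow fibre transcripts varied widely between mice of a group. Myh7, the slow type 1 myosin heavy chain, measured 12.3 ± 9.69 RPKM in WT untrained, 51.3 ± 11.9 in WT trained, 31.7 ± 22.6 in KO untrained and 27.8 ± 27.6 in KO trained muscle (SD, n = 4), and Tnnt1, slow troponin T, 26.1 ± 15.7, 89.8 ± 19.1, 54.9 ± 34.1 and 46.9 ± 40.4. Within KO trained muscle, Myh7 ran from 8.24 in library 4 to 68.4 in library 3.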
